A study of Homo sapiens with 8 samples.

How the data were processed

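RNA captured with biotin-tagged Msi1, GFP or PABP1 from HEK293T cells was hybridised to 8 Agilent human arrays in 2 colours. Per the labels' protocols, tagged complexes were collected on streptavidin beads 48 hours after transfection, protein was digested, RNA was extracted with phenol and chloroform, and labelled cRNA was made with a linear amplification kit. Dyes and replicate numbers came from the labels. Each experiment had 4 arrays, 2 per dye orientation, and every array lay on a slide of its own. Total RNA of the cells was not analysed here.

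Per the file headers, the mean spot and median local background values are intensity values of the Cy3 and Cy5 channels, extracted with Agilent Feature Extraction versions of the 9.1 line, while the submitters' processing notes name version 8.5. The processed intensity values in the same deposited tables were background-subtracted with spatial detrending and dye-normalized by rank-selected LOWESS inside Feature Extraction, per the file headers. The authors also deposited a value table of log2 ratios of red over green. Its 21073 rows were matched by row number and set against each array's own ratios, which gave correlations of 0.987 to 0.999 and slopes of 0.911 to 0.959 over spots with a signal of at least 500 in both channels, so scale and direction follow from the data and the method of centring stays unknown. Its column medians were 0.00586, 0.00372, 0.0112 and 0.00623 in the GFP experiment and 0.00275, −0.0151, 0.00867 and −0.00202 in the PABP1 experiment, each in the order Cy3 replicates 1 and 2, then Cy5 replicates 1 and 2 for Msi1. It served as an alternative.

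Signals were corrected with normexp (offset 50) on all spots and normalized by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3, with the data.table package (version 1.17.8) for reading and matplotlib 3.10.9 for plots. Control spots and spots marked as outliers, 51 to 355 per array, were left out, and saturated spots, 11 to 106 per array, were kept. Among genes named here, apart from EVX1, the probes of CSNK1E and SNRPG were saturated on at most 2 arrays of an arm and those of BBC3, EEF2, MED13L, RPL10, RPL18 and RPL39 on 1, so that their ratios are less exact. Signs were turned so that every ratio is Msi1 over the control, and spots of a probe were averaged. Probes were kept where well above background on at least 2 of 4 arrays in at least 1 of the 4 RNA arms. Genes with several probes were represented by the probe of highest mean signal. Of 20173 probes, 16246 were named through their accession, 1068 through a current symbol and 506 through a synonym in a RefSeq gene table of assembly GRCh38.p14, and 2353 kept the name of the array file. No positions are given, since no genome build is stated for the array. Of 1321 genes with more than a single tested probe, 38 had probes called in opposite directions against GFP and 84 against PABP1. Probes of near-identical genes (HSPA1A and HSPA1B, RPL10 and RPL10L, the replication-dependent histones) can read more than their own transcript.

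All 8 arrays entered a single limma fit with a coefficient per experiment and a dye term shared by the arrays, tested with eBayes at a Benjamini-Hochberg adjusted p of 0.05 per comparison. The tests were Msi1 over GFP, Msi1 over PABP1 and the difference between these ratios. The design, the alternatives, the gene lists and the rule for named genes were written before the data were examined. That rule takes the 10 highest and 10 lowest genes with a symbol, a passing adjusted p and the same sign on all 4 arrays per comparison, the 15 genes with the highest smaller ratio among those above both controls, the 6 largest differences in each direction, MSI1, MSI2, PABPC1, the described Musashi1 targets and up to 4 members per gene list. The 21 lists covered described Musashi1 targets, the Notch and Wnt pathways, cell cycle, apoptosis, ubiquitin-conjugating enzymes, proteasome subunits, cytosolic ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, histones, ZNF zinc finger genes, hnRNP and SR splicing proteins, heat shock and endoplasmic reticulum stress, the interferon response, immediate early genes, solute carriers, neural progenitor and neuronal genes, markers of other tissues and nuclear noncoding RNAs. Lists defined by a name pattern matched old and updated symbols, so the oxidative phosphorylation list also holds EMC8 and DMAC2L and the ZNF list RNF114 and ZMYM2. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, which asks whether a list's genes move on balance in a single direction, with Benjamini-Hochberg adjustment over lists per comparison. Fry does not set a list against the other genes. With 9638 genes called against GFP and 10715 against PABP1, it can call a list that moves no more than genes in general. The camera calls, 18 in the comparisons with GFP and PABP1, included 0 that held with an estimated correlation.

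Where a probe was not well above background, or was saturated, on every array of an arm, its fold is a bound, taken from channel values after loess and Aquantile normalization as the brighter arm's mean against the dimmer arm's mean of the higher of the probe's own signal and the lowest signal well above background on that array. Such bounds applied to 281 genes for Msi1 over GFP, 289 for GFP over Msi1, 62 for Msi1 over PABP1 and 534 for PABP1 over Msi1. The fit was tested on simulated log2 ratios for the 16193 genes. In each comparison with a control, 50 genes were changed by each size, far fewer than were called in the real arrays. Rates of recovery and false calls therefore need not hold for the real arrays. For Msi1 over GFP the fit recovered 34.0% of simulated log2 changes of 0.25, 86.0% of 0.5 and 100% of 1, with 5.33% of calls false, and for Msi1 over PABP1 26.0%, 74.0% and 100%, with 6.25% false. For the difference the fit recovered 14.0%, 61.2% and 100%, with 4.18% false. The median SE was 0.0625 against GFP and 0.0623 against PABP1. Alternatives changed the background correction, the normalization within and between arrays, the source of the values, the filter on dim probes, the probes per gene, the dye term, the arrays in the fit, the replicate number as a block, the threshold, the set test and the arrays kept.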

Results

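Messenger RNA held by the RNA-binding protein Musashi1 (Msi1) was measured in HEK293T cells, a human embryonic kidney cell line that is easy to transfect. Cells made Msi1, green fluorescent protein (GFP) or poly(A)-binding protein 1 (PABP1), each fused to a peptide that the cell tags with biotin. At 48 hours the tagged protein and the RNA bound to it were captured on streptavidin beads, and the RNA was amplified, labelled and hybridised to Agilent human arrays in 2 colours. In the GFP experiment, 4 arrays set Msi1 RNA against GFP RNA, and in the PABP1 experiment 4 arrays set Msi1 RNA against PABP1 RNA. Each experiment held 2 arrays with Msi1 in Cy3 and 2 with Msi1 in Cy5. Each array gave 21073 spots other than controls, and 16193 genes were tested. The median spot signal was 110.9 to 131.3 for Msi1 and 102.2 to 141.7 for GFP in the GFP experiment, and 152.5 to 210.4 for Msi1 and 139.5 to 225.4 for PABP1 in the PABP1 experiment. Between 70.2% and 91.5% of spots were well above background in a channel. The number of arrays limits the precision. Correlations of the log2 ratios across genes were 0.928 to 0.981 between arrays of the GFP experiment, 0.901 to 0.96 within the PABP1 experiment and 0.626 to 0.72 between the experiments. Below, ratios are log2 of Msi1 over the control ± SE from limma, with n = 4 arrays unless another n is given.

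The GFP comparison asks which mRNAs held a larger share of the RNA recovered with Msi1 than with GFP. GFP stands for RNA that sticks to beads, tag and an unrelated protein. RNA was amplified and each array normalized, with medians over all genes of −0.013 against GFP and −0.034 against PABP1. Ratios are therefore relative to the other genes, and higher or lower does not give the amount of an mRNA recovered. The genes with the highest ratios were PCLAF, which encodes a PCNA-binding factor (2.54 ± 0.052, 5.81-fold higher than GFP), TMCO1, an endoplasmic reticulum membrane protein (2.45 ± 0.050, 5.46-fold), and MYCBP, a Myc-binding protein (2.20 ± 0.095). MRPL50 of the mitochondrial ribosome reached 2.18 ± 0.052, SDE2, a factor of DNA replication stress, 2.15 ± 0.064, and ARL6IP1, a shaper of the endoplasmic reticulum, 2.08 ± 0.060. ATP6V1G1 of the vacuolar proton pump (2.06 ± 0.062), SDHAF3, an assembly factor of succinate dehydrogenase (2.06 ± 0.091), MMADHC of cobalamin metabolism (2.05 ± 0.062) and PIGF of GPI anchor synthesis (2.04 ± 0.057) completed the highest 10. The lowest ratio among genes measured on all 4 arrays was that of HSPA6, a heat-inducible Hsp70 chaperone, at −5.04 ± 0.099 or 32.9-fold lower than GFP, followed by its cochaperone DNAJB1 at −3.15 ± 0.065 or 8.85-fold lower.

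Ribosomal protein mRNAs made up much of the rest of the low end of the GFP comparison, with RPS29 at −2.84 ± 0.095 and RPL18 at −2.66 ± 0.050. APRT, a purine salvage enzyme (−2.69 ± 0.086), NME3, a nucleoside diphosphate kinase (−2.67 ± 0.092), P4HB, a protein disulfide isomerase (−2.64 ± 0.069), and CACNG6, a calcium channel subunit (−2.69 ± 0.104), were also among the lowest 10. All of the named highest and lowest genes had the same sign on their 4 arrays, and the largest limma adjusted p among them was 1.21e-08, that of SDHAF3. In all, 4533 genes were higher and 5105 lower in Msi1 than in GFP, of which 779 and 1491 differed at least 2-fold.

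Among mRNAs described as Musashi1 targets, NUMB, which encodes an inhibitor of Notch signalling, was higher with Msi1 than with GFP (0.78 ± 0.069, adjusted p = 1.99e-06 with limma). APC of the Wnt pathway (0.49 ± 0.083, adjusted p = 0.000358 with limma) and CDKN1A, the cell cycle inhibitor p21 (0.30 ± 0.067, adjusted p = 0.00275 with limma), were higher by less. ROBO3, an axon guidance receptor, was lower (−1.70 ± 0.055), and DCX, a microtubule protein of migrating neurons, did not pass the test (−0.01 ± 0.049). Of these 5 members, 3 were higher and 1 lower, with the same counts adjusted over the list alone. Their median was 0.30, or 0.58 with median centring, and their mean −0.03. Camera did not call the list (adjusted p = 0.63, and adjusted p = 0.668 with an estimated correlation), and fry gave a net direction downward (adjusted p = 0.00213). ROBO3 was the only member called lower, so that direction rests on it. MSI1 itself was at −0.09 ± 0.100 (adjusted p = 0.488 with limma), where the position of the probe against the construct is not known, and its paralog MSI2 was at 0.08 ± 0.055. MSI2 passed the test under 4 other settings, at 0.18 to 0.62, the last of these from a dimmer probe.

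The list of cytosolic ribosomal proteins held 70 lower and 6 higher of 79 members tested against GFP, with the same counts adjusted over the list alone and a median of −1.52. RPL10, at −2.88 ± 0.099 (n = 3), was the lowest of them. The median was −1.60 on arrays of the earlier number and −1.40 on those of the later number, each pair sharing a scan day. Camera called the list lower at the preset correlation (adjusted p = 6.65e-17), but not with an estimated correlation (adjusted p = 0.177). Fry gave it a net direction downward (adjusted p = 8.42e-07). Nuclear-encoded oxidative phosphorylation genes were lower in 52 of 80 and higher in 19, or 53 and 20 adjusted over the list alone. Their median was −0.50 and their preset-correlation adjusted p was 0.00176 (adjusted p = 0.345 with an estimated correlation), and median centring in place of loess moved the median to −0.10 and ended the call. NDUFA11 of complex I (−2.27 ± 0.097) and UQCRC1 of complex III (−2.15 ± 0.081) were among its lowest members.

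Heat shock and endoplasmic reticulum stress genes were lower than with GFP in 16 of 20 and higher in 4, with the same counts adjusted over the list alone and a median of −0.77 that became −0.34 with median centring. Besides HSPA6 and DNAJB1, the lowest members were TRIB3, a pseudokinase of the stress response (−1.87 ± 0.077), and HSPA1A, an Hsp70 whose copy HSPA1B is near-identical (−1.81 ± 0.095), and a further HSPA1A probe gave −1.66. Camera gave the list an adjusted p of 0.00234 at the preset correlation (adjusted p = 0.345 with an estimated correlation, and 0.0602 with median centring). Translation factors were lower in 39 of 75 and higher in 20, unchanged in number adjusted over the list alone, with a median of −0.25 that became 0.03 with median centring. EIF3C of the initiation machinery was at −2.32 ± 0.063 and EEF1D of elongation at −2.29 ± 0.059, and camera gave an adjusted p of 0.0278 (adjusted p = 0.471 with an estimated correlation, and 0.0539 to 0.684 under 4 other settings). That list's name pattern also took in the electron transfer flavoproteins and the Argonautes under older names. Proteasome subunits were lower in 26 of 45 and higher in 11, the same adjusted over the list alone, with a median of −0.28 that became 0.01 with median centring and an adjusted p of 0.0278 (adjusted p = 0.471 with an estimated correlation, and 0.0557 to 0.905 under 4 other settings). PSMA7 of the core particle (−2.04 ± 0.056) and PSMC3 of its ATPase ring (−1.63 ± 0.117) were the members furthest from 0.

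Groups that were higher with Msi1 than with GFP included proteins of RNA processing and ubiquitin transfer. Splicing proteins of the hnRNP and SR families were higher in 22 of 39 and lower in 8, with the same counts adjusted over the list alone and a median of 0.50. SREK1 (1.29 ± 0.062) and SRSF6 (1.24 ± 0.090), both with SR domains, stood highest, while HNRNPM was lower (−1.29 ± 0.061). Camera gave the list an adjusted p of 0.00234 at the preset correlation (adjusted p = 0.345 with an estimated correlation). Ubiquitin-conjugating enzymes were higher in 19 of 31 and lower in 6, also adjusted over the list alone, with a median of 0.34. UBE2E3 was at 1.99 ± 0.065 (n = 3), and UBE2M, which transfers NEDD8, and UBE2S went the other way, at −2.17 ± 0.073 and −1.76 ± 0.082. The list had an adjusted p of 0.00763 (adjusted p = 0.177 with an estimated correlation). ZNF zinc finger genes were higher in 184 of 385 and lower in 77, or 185 and 78 adjusted over the list alone, with a median of 0.14 and an adjusted p of 0.00204 (adjusted p = 0.58 with an estimated correlation). The ZNF members furthest from 0 were lower, ZNF598, a ligase of stalled ribosomes, at −2.09 ± 0.060 and ZNF579 at −2.08 ± 0.045. Histones were higher in 36 of 70 and lower in 14, or 38 and 14 adjusted over the list alone, with a median of 0.20, although the linker histone H1-2 was at −2.29 ± 0.054. Their adjusted p was 0.0178 (adjusted p = 0.634 with an estimated correlation, and 0.0602 with median centring).

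The other lists were not called by camera against GFP. Notch pathway genes were higher in 5 of 26 and lower in 10, also adjusted over the list alone (median −0.05, adjusted p = 0.657, and adjusted p = 0.831 with an estimated correlation). The target HEY1 was at 1.11 ± 0.081 and the ligand JAG2 at −1.28 ± 0.089. Wnt pathway genes were higher in 10 of 32 and lower in 12, also adjusted over the list alone, with a median of 0.05, a mean of −0.19 and camera's direction downward (adjusted p = 0.838, and adjusted p = 0.924 with an estimated correlation). AXIN1, the scaffold of the complex that degrades beta-catenin, was at −2.29 ± 0.058 and the signal transducer DVL1 at −1.80 ± 0.061. Cell cycle genes divided, with 19 of 41 higher and 15 lower, also adjusted over the list alone. Their median was 0.08 and their mean −0.03, with camera's direction upward (adjusted p = 0.645, and adjusted p = 0.725 with an estimated correlation). CCNA2, cyclin A2, was at 1.53 ± 0.050, the replication helicase subunit MCM5 at −1.66 ± 0.079 and the kinase CDK4 at −1.60 ± 0.083. Apoptosis genes were higher in 13 of 29 and lower in 7, also adjusted over the list alone (median 0.12, adjusted p = 0.158, and adjusted p = 0.345 with an estimated correlation), among them the death receptor FAS at 1.44 ± 0.062 and the BCL2 antagonist BAD at −1.81 ± 0.090.

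Interferon response genes were higher than with GFP in 7 of 18 and lower in 3, also adjusted over the list alone (median 0.07, or 0.49 with Agilent processed signals, adjusted p = 0.297, and adjusted p = 0.471 with an estimated correlation). ISG15 was at −1.29 ± 0.072 and IRF7 at −1.36 ± 0.119. Immediate early genes were higher in 5 of 16 and lower in 7, or 5 and 9 adjusted over the list alone (median −0.14, adjusted p = 0.516, and adjusted p = 0.649 with an estimated correlation). KLF10 was at 1.41 ± 0.112 and the transcription factors JUN and JUND were at −1.10 ± 0.128 and −1.33 ± 0.068 (n = 3 for JUND). Solute carriers were higher in 83 of 312 and lower in 87, or 80 and 85 adjusted over the list alone. Their median was −0.01 with camera's direction upward (adjusted p = 0.838, and adjusted p = 0.904 with an estimated correlation). The mitochondrial citrate carrier SLC25A1 was at −1.88 ± 0.079. Neural progenitor and neuronal genes were higher in 3 of 18 and lower in 6, also adjusted over the list alone (median −0.02, adjusted p = 0.75, and adjusted p = 0.904 with an estimated correlation). The neurofilament gene NEFM was at −2.49 ± 0.087 and INA, another intermediate filament gene, at 0.92 ± 0.081. Markers of other tissues held 0 higher and 8 lower of 17, also adjusted over the list alone (median −0.16, adjusted p = 0.163, and adjusted p = 0.634 with an estimated correlation). The keratin KRT10 was at −0.61 ± 0.058. Its call was lost with median centring, at −0.23 with an adjusted p of 0.0679 from limma. Of the nuclear noncoding RNAs, 2 were tested, and 1 was higher and 0 lower, also adjusted over the list alone (adjusted p = 0.838, and adjusted p = 0.906 with an estimated correlation). That RNA was MALAT1 at 0.38 ± 0.118 (adjusted p = 0.0172 with limma), with adjusted p values of 0.0531 to 0.0595 without any 1 of 3 of the 4 GFP arrays (both with Msi1 in Cy5, and that of replicate 1 with Msi1 in Cy3). No member of the list of mitochondrially encoded transcripts was tested by symbol. Among these lists, fry gave a net direction downward for Notch (adjusted p = 0.0132), Wnt (0.00332), immediate early (0.000455), neural (0.0042) and other-tissue marker genes (0.00503). Fry's direction was upward for apoptosis (adjusted p = 1.48e-05) and interferon response genes (0.00332). Cell cycle genes, solute carriers and nuclear noncoding RNAs were not called by fry (adjusted p = 0.214 to 0.819).

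Nothing states that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Several named genes had a further probe with another size against GFP, among them SDE2 (0.08), ELOB (−0.05), CACNG6 (−0.47), JUND (−0.66), DVL1 (−0.85), ROBO3 (−0.86) and ZNF598 (−1.37).

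**Figure D1:**
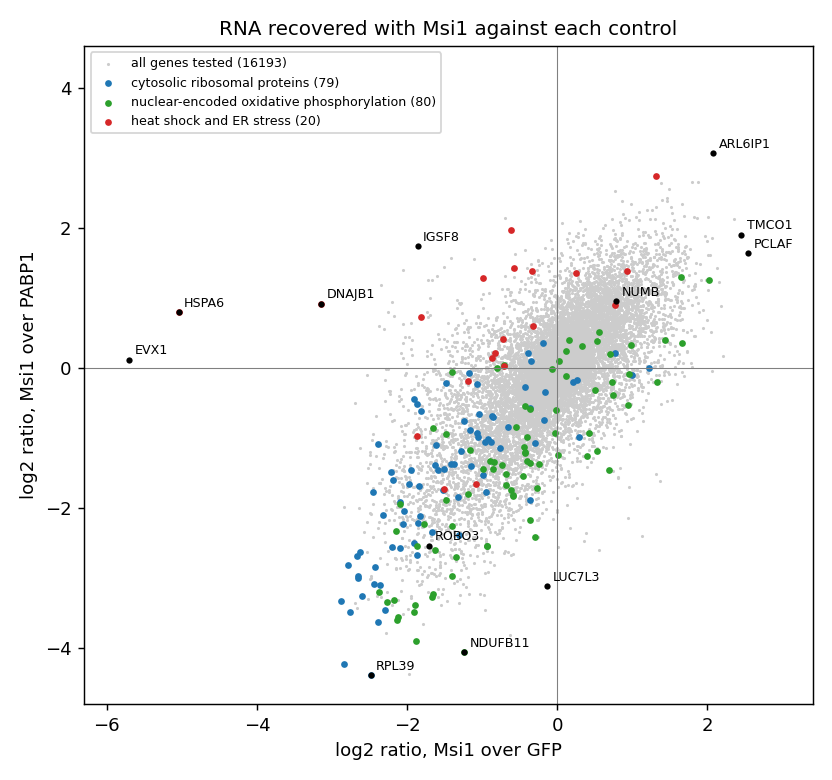
Each point is a gene, with the log2 ratio of Msi1 over GFP on the horizontal axis and of Msi1 over PABP1 on the vertical axis, both fitted over 4 arrays per experiment. Most of the 79 cytosolic ribosomal protein genes and 80 oxidative phosphorylation genes lie at the lower left, and HSPA6, DNAJB1 and EVX1 lie at the far left above 0 on the vertical axis.

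The PABP1 comparison asks which mRNAs held a larger share with Msi1 than with a protein that binds poly(A) tails in general. ARL6IP1 had the highest ratio (3.07 ± 0.060, 8.38-fold higher than PABP1), followed by HERPUD1, a gene of the degradation of misfolded endoplasmic reticulum proteins (2.75 ± 0.057), RCN2, a calcium-binding protein of the same compartment (2.66 ± 0.065), and DHRS2, a short-chain dehydrogenase (2.65 ± 0.067). LBR, the lamin B receptor, was at 2.64 ± 0.104, OSTM1, a partner of a lysosomal chloride transporter, at 2.56 ± 0.068 and OBI1, a ubiquitin ligase of replication origins, at 2.53 ± 0.076. BTG3, an antiproliferative gene (2.43 ± 0.093), RNF149, a ubiquitin ligase (2.39 ± 0.082), and ZFAND5 (2.39 ± 0.060) followed. The lowest ratios belonged to RPL39 of the ribosome (−4.38 ± 0.065, 20.9-fold lower than PABP1) and SSR4 of the translocon-associated complex (−4.36 ± 0.092, 20.6-fold lower).

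Below these in size came RPS29 (−4.23 ± 0.095), NDUFB11 of complex I (−4.05 ± 0.107), COX8A of complex IV (−3.90 ± 0.064), the elongin subunit ELOB (−3.78 ± 0.092), the RNA polymerase II subunit POLR2L (−3.65 ± 0.075), RPL10L (−3.63 ± 0.080), ATP5F1E of the ATP synthase (−3.60 ± 0.078) and NDUFS8 of complex I (−3.55 ± 0.074). The RPL10L probe can also read the near-identical RPL10. All of these genes had the same sign on their 4 arrays, with a largest limma adjusted p of 3.17e-09, that of LBR. In all, 5062 genes were higher and 5653 lower in Msi1 than in PABP1, of which 1066 and 1838 differed at least 2-fold.

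Among the described Musashi1 targets, 3 were higher than with PABP1, with APC at 1.48 ± 0.083, NUMB at 0.95 ± 0.069 and CDKN1A at 0.77 ± 0.067, the largest limma adjusted p being 1.58e-06. ROBO3 was lower (−2.54 ± 0.055, with −1.62 from a dimmer probe) and DCX, well above background on 2 of 4 arrays in the Msi1 channel, did not pass (−0.08 ± 0.049). Again 3 of 5 were higher and 1 lower, also adjusted over the list alone, with a median of 0.77 and a mean of 0.12. The list was not called by camera (adjusted p = 0.388, and adjusted p = 0.462 with an estimated correlation), while fry gave a net direction downward (adjusted p = 0.00656). That direction again rests on ROBO3, the only member called lower. MSI1 was lower (−0.62 ± 0.100) as was MSI2 (−0.42 ± 0.055), whose dimmer probe gave 0.36, on the other side. PABPC1, the gene of PABP1, was usable on 1 of the 4 GFP arrays, was not tested, and lay between −0.34 and 0.39 on the PABP1 arrays.

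**Figure D2:**
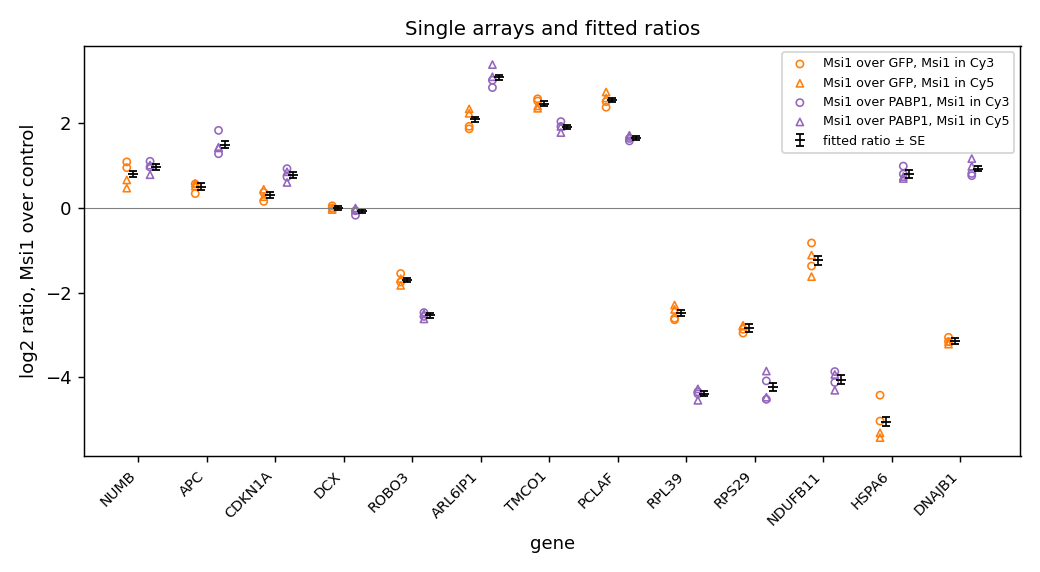
Each open point is the log2 ratio of Msi1 over GFP (orange) or PABP1 (purple) on a single array, for the gene on the horizontal axis, with Msi1 in Cy3 as circles and in Cy5 as triangles, and bars give the fitted ratio ± SE. NUMB lay above 0 on all arrays, ROBO3 below 0 on all, and HSPA6 below 0 against GFP (fitted −5.04) and above 0 against PABP1 (fitted 0.80).

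Cytosolic ribosomal protein genes were lower than with PABP1 in 70 of 79 and higher in 1, also adjusted over the list alone, with a median of −1.44 (−1.34 on arrays numbered 1 and −1.63 on those numbered 2, which share a scan day). Camera's adjusted p was 2.01e-15 (adjusted p = 0.161 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were lower in 62 of 80 and higher in 11, also adjusted over the list alone, with a median of −1.33 and an adjusted p of 1.51e-10 (adjusted p = 0.161 with an estimated correlation). Proteasome subunits were lower in 29 of 45 and higher in 5, also adjusted over the list alone (median −0.39, adjusted p = 0.00152, and adjusted p = 0.331 with an estimated correlation), among them PSMB3 (−3.33 ± 0.104) and the immunoproteasome subunit PSMB10 (−2.16 ± 0.083). Histones were lower in 35 of 70 and higher in 13, also adjusted over the list alone, with a median of −0.17 and an adjusted p of 0.046 (adjusted p = 0.522 with an estimated correlation). H4C13 was at −2.91 ± 0.106 and H2AC18 at −2.87 ± 0.082, the latter with −0.64 from a dimmer probe. The histone call was also lost under 4 other settings, with adjusted p values of 0.0501 to 0.087, and at 0.0523 to 0.0751 without the GFP array of replicate 2 with Msi1 in Cy3 or either PABP1 array of replicate 1.

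Heat shock and endoplasmic reticulum stress genes went the other way from the GFP comparison, with 13 of 20 higher than with PABP1 and 4 lower, also adjusted over the list alone, and a median of 0.76. HERPUD1 stood highest, the chaperone HSP90AA1 was at 1.97 ± 0.059, and the small heat shock protein HSPB1 (−1.73 ± 0.075) and CHAC1, a glutathione-degrading enzyme (−1.66 ± 0.074), were lower. Camera gave an adjusted p of 0.00276 (adjusted p = 0.357 with an estimated correlation, and 0.0609 with median centring). Immediate early genes were higher in 12 of 16 and lower in 1, also adjusted over the list alone (median 0.38, adjusted p = 0.00186, and adjusted p = 0.161 with an estimated correlation). KLF10 was at 1.63 ± 0.112, IER5 at 1.57 ± 0.060 and JUN at 1.55 ± 0.128. Splicing proteins of the hnRNP and SR families were higher in 26 of 39 and lower in 6, or 26 and 7 adjusted over the list alone (median 0.38, adjusted p = 0.00186, and adjusted p = 0.331 with an estimated correlation). HNRNPK was at 1.94 ± 0.082 and HNRNPR at 1.55 ± 0.059, and median centring put the list's adjusted p at 0.0508. Among ZNF zinc finger genes 198 of 385 were higher and 94 lower, or 201 and 96 adjusted over the list alone (median 0.18, adjusted p = 0.00263, and adjusted p = 0.462 with an estimated correlation). ZNF664 was at 2.13 ± 0.069 and ZNF593 at −2.93 ± 0.062. Wnt pathway genes were higher in 17 of 32 and lower in 8, also adjusted over the list alone (median 0.21, adjusted p = 0.046, and adjusted p = 0.462 with an estimated correlation). The receptors FZD5 was at 1.47 ± 0.071 and FZD2 at −2.28 ± 0.066. Leaving out any of 3 PABP1 arrays (both of replicate 1, and replicate 2 with Msi1 in Cy5) put its adjusted p at 0.0635 to 0.0735, and 3 other settings at 0.0501 to 0.166.

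Camera did not call the remaining lists against PABP1. Translation factors were lower in 40 of 75 and higher in 23, or 41 and 23 adjusted over the list alone (median −0.21, adjusted p = 0.0734, and adjusted p = 0.462 with an estimated correlation). EIF4G2 was at 2.26 ± 0.087, EIF4A2 at 2.23 ± 0.090 and EIF6 at −2.45 ± 0.063. Notch pathway genes were higher in 10 of 26 and lower in 5, or 10 and 4 adjusted over the list alone, with a median of −0.01 whose sign changed with the scaling, a mean of 0.16 and camera's direction upward (adjusted p = 0.201, and adjusted p = 0.462 with an estimated correlation). RBPJ, the transcription factor of Notch signalling, was at 1.46 ± 0.109, the protease ADAM17 at 0.98 ± 0.059 and the glycosyltransferase RFNG at −1.43 ± 0.078. Cell cycle genes were higher in 21 of 41 and lower in 13, also adjusted over the list alone (median 0.20, or 0.40 with the deposited value table, adjusted p = 0.114, and adjusted p = 0.41 with an estimated correlation). E2F3 was at 2.10 ± 0.058, the retinoblastoma gene RB1 at 1.89 ± 0.061 and E2F1 at −1.63 ± 0.067, and a dimmer E2F3 probe gave 0.23. Apoptosis genes were higher in 13 of 29 and lower in 10, also adjusted over the list alone, with a median of −0.01 whose sign changed with the scaling, a mean of 0.03 and camera's direction upward (adjusted p = 0.388, and adjusted p = 0.462 with an estimated correlation). BAD was at −3.04 ± 0.090 and the pore-forming BAX at −1.80 ± 0.070. Ubiquitin-conjugating enzymes were higher in 12 of 31 and lower in 11, or 13 and 11 adjusted over the list alone (median 0.07, adjusted p = 0.388, and adjusted p = 0.462 with an estimated correlation). UBE2E3 was at 1.82 ± 0.055 and UBE2M at −2.17 ± 0.073.

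Interferon response genes were higher than with PABP1 in 7 of 18 and lower in 2, or 5 and 2 adjusted over the list alone, with a median of 0.07, a mean of −0.03 and camera's direction upward (adjusted p = 0.388, and adjusted p = 0.462 with an estimated correlation). ISG15 was at −1.89 ± 0.072. Solute carriers were higher in 93 of 312 and lower in 98, or 92 and 97 adjusted over the list alone, with a median of −0.03, a mean of −0.08 and camera's direction upward (adjusted p = 0.979, and adjusted p = 0.984 with an estimated correlation). The mitochondrial carrier SLC25A11 was at −2.62 ± 0.057. Neural genes were higher in 3 of 18 and lower in 4, also adjusted over the list alone, with a median of 0.02 whose sign changed with the scaling, a mean of −0.08 and camera's direction upward (adjusted p = 0.922, and adjusted p = 0.973 with an estimated correlation). NEFM was at −1.20 ± 0.103 (n = 3). Markers of other tissues were higher in 1 of 17 and lower in 10, also adjusted over the list alone (median −0.16, adjusted p = 0.153, and adjusted p = 0.479 with an estimated correlation). KRT10 was at −1.74 ± 0.058. Of the pair of nuclear noncoding RNAs tested, MALAT1 was higher (1.78 ± 0.118) and TUG1 lower (−0.66 ± 0.099), also adjusted over the list alone (adjusted p = 0.781, and adjusted p = 0.872 with an estimated correlation). Among lists not called by camera, fry's direction was upward for Notch (adjusted p = 0.000636), cell cycle (9.26e-05), apoptosis (0.000535), ubiquitin-conjugating (2.38e-05) and nuclear noncoding genes (0.022). Fry's direction was downward for translation factors (adjusted p = 1.06e-05), solute carriers (0.00161) and other-tissue markers (0.000535). Interferon response and neural genes were not called by fry (adjusted p = 0.39 and 0.233). Further probes differed in size for ELOB (−1.64 against PABP1) and FZD5 (0.07 and 0.16).

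**Figure D3:**
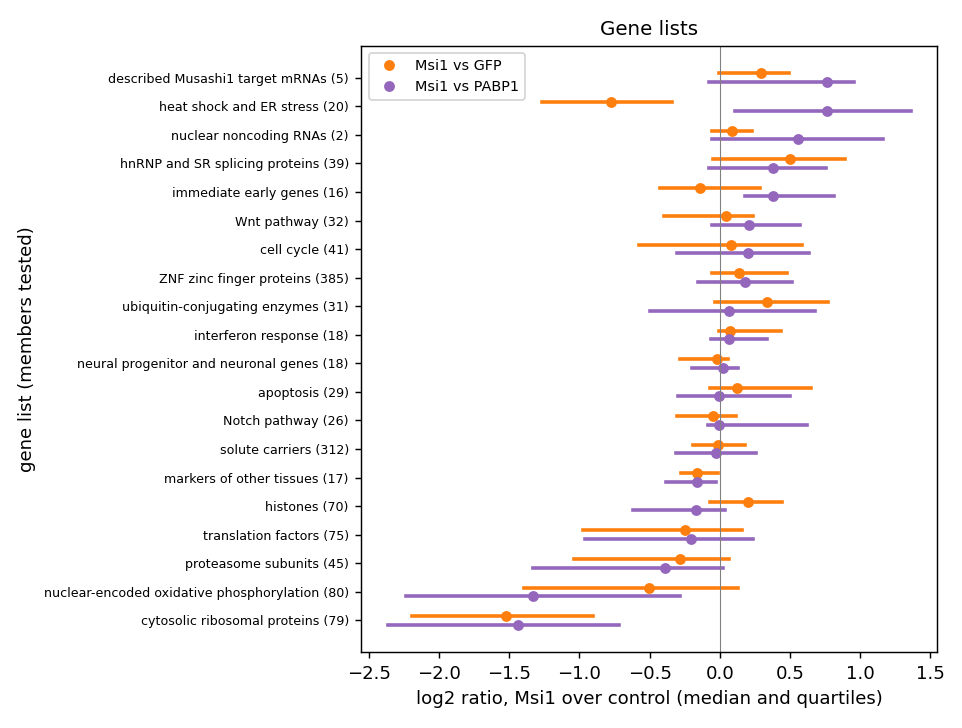
Points are the median log2 ratio of each gene list's tested members, over GFP in orange and over PABP1 in purple, and lines run from the lower to the upper quartile. Cytosolic ribosomal proteins lay lowest against both controls (−1.52 and −1.44), and heat shock and endoplasmic reticulum stress genes lay below 0 against GFP (−0.77) and above 0 against PABP1 (0.76).

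Genes above both controls held a larger share of the RNA with Msi1 than with an unrelated protein and with a general mRNA-binding protein. ARL6IP1 (2.08 and 3.07 over GFP and PABP1), FBXO28 of a ubiquitin ligase (2.01 ± 0.059 and 2.16 ± 0.059), TMCO1 (2.45 and 1.90 ± 0.050) and DHRS2 (1.87 ± 0.067 and 2.65) had the highest of the smaller ratios. GPR137B, a lysosomal membrane protein, ATP6V1G1, SPCS2 of the signal peptidase (1.82 ± 0.065 and 2.15 ± 0.065) and RCN2 followed, and then the homeobox gene PKNOX1 and PMAIP1, a proapoptotic BCL2 relative (1.76 ± 0.070 and 1.70 ± 0.070). PTBP2, a splicing regulator of neurons (1.70 ± 0.057 and 1.73 ± 0.057), HSD17B6, RAB11A of recycling endosomes (1.67 ± 0.083 and 2.34 ± 0.083), DEPDC1 and PCLAF completed the 15 genes with the highest smaller ratio. In all, 3302 genes were higher against both controls, where independent lists would share 1417, and 365 at least 2-fold, where independent lists would share 51.3. Lower against both were 3704 genes, with 1782 for independent lists. Across the 16193 genes, which are not independent replicates, the ratios had a Pearson r of 0.703 and a Spearman rho of 0.664, and 74.0% of genes had the same sign. The sources used here do not say whether the same Msi1 RNA was hybridised in both experiments. In 20 simulations of unchanged genes with a shared Msi1 RNA, r was 0.5, the covariance was 0.00295 against 0.369 observed, and 0 genes were called higher against both. These simulations covered array noise alone.

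The contrast of the ratios, Msi1 over GFP minus Msi1 over PABP1, asks where the controls gave different answers and equals PABP1 over GFP if Msi1 RNA was alike in both. Apart from EVX1, a homeobox gene whose saturated probe gave only a limit, the largest negative differences were those of HSPA6 (−5.84), DNAJB1 (−4.07), the immunoglobulin superfamily gene IGSF8 (−3.60), CRTC1, a CREB coactivator (−3.53), and BBC3, a proapoptotic BCL2 relative (−3.15). HSPA6, DNAJB1, IGSF8 (−1.86 ± 0.082 and 1.74 ± 0.082), CRTC1 (−2.34 ± 0.122 and 1.19 ± 0.122) and BBC3 (−2.20 ± 0.150, n = 3, and 0.95 ± 0.126) were lower than GFP and higher than PABP1. A dimmer BBC3 probe gave a smaller ratio over GFP (−0.64) and 1.05 over PABP1. Among the largest positive differences were those of MED13L of the Mediator complex (3.09), LUC7L3, a splicing factor (2.98), NDUFB11 (2.81), APOC1, an apolipoprotein (2.49), and SSR4 (2.39). Of these, LUC7L3 (−0.14 ± 0.069 over GFP) differed from PABP1 alone. MED13L, with fewer than 4 usable arrays over GFP, had probes in opposite directions, the dimmer at −0.48 and 1.02.

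EVX1 was saturated in the GFP channel on all 4 arrays and was at least 52-fold lower with Msi1 than with GFP (adjusted p = 8.66e-10 with limma, n = 3 usable arrays), yet a dimmer EVX1 probe gave −0.73. In all, 7833 genes differed, 4071 with a positive and 3762 with a negative difference. The lists with a different shift were oxidative phosphorylation (median difference 0.85, with 62 of 80 members positive and 6 negative, also adjusted over the list alone, adjusted p = 5.08e-14, and adjusted p = 0.0737 with an estimated correlation) and histones (0.56, with 42 positive and 6 negative of 70, or 45 and 6 adjusted over the list alone, adjusted p = 7.78e-06, and adjusted p = 0.42 with an estimated correlation). COX7B of complex IV went from −0.30 ± 0.086 over GFP to −2.41 ± 0.086 over PABP1. Heat shock and endoplasmic reticulum stress genes had a median difference of −1.07, with 17 of 20 negative and 1 positive, also adjusted over the list alone (adjusted p = 2.01e-09, and adjusted p = 0.0857 with an estimated correlation). Immediate early genes had −0.52, with 13 of 16 negative and 1 positive, also adjusted over the list alone (adjusted p = 8.39e-06, and adjusted p = 0.0737 with an estimated correlation). Smaller shifts were called for Wnt pathway genes (−0.23, 16 of 32 negative and 3 positive, or 17 and 4 adjusted over the list alone, adjusted p = 0.00796, and adjusted p = 0.42 with an estimated correlation) and proteasome subunits (0.23, or 0.81 with median centring, 23 of 45 positive and 6 negative, or 25 and 6 adjusted over the list alone, adjusted p = 0.0139, and adjusted p = 0.42 with an estimated correlation or 0.169 with scale normalization). Ubiquitin-conjugating enzymes had 0.17 (13 of 31 positive and 2 negative, also adjusted over the list alone, adjusted p = 0.0255, and adjusted p = 0.154 with an estimated correlation or 0.0665 with the strict filter). The experiments were scanned on different days, so the control and the day cannot be told apart in this contrast.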

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

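The limma test of the difference between the ratios was planned, whereas the tests of explanations and the counts of other array groupings below were chosen after the results were seen. Heat shock and endoplasmic reticulum stress transcripts stood out as a list, with 16 of 20 lower with Msi1 than with GFP and 13 higher than with PABP1. The 4 that were higher than with GFP were also higher than with PABP1, and the 4 lower than with PABP1 were also lower than with GFP. HSPA6 differed by −5.84 between the ratios, DNAJB1 by −4.07, HSP90AA1 by −2.59 and HSPA1A by −2.54 (limma). Against GFP, 2.02% of 10000 random lists matched on signal had a median as low as the heat shock list. Its median against PABP1 lay above 99.7% of such lists.

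A fault of a single scan day is argued against for this heat shock pattern, since with either day of the GFP experiment alone the list's median difference stayed at −1.05 or lower. A few cross-reacting probes are also argued against, because 17 of the 20 members had a difference called below 0. The size changed with the scaling, as median centring left a median difference of −0.38 and the deposited value table −1.004, and the cause was not tested. A candidate explanation is that cells making GFP, a foreign protein, held more of these mRNAs, but total RNA was not analysed here. It could give the list's median of −0.77 against GFP. It could not give the median of 0.76 against PABP1, since no GFP RNA was hybridised in that experiment. A change in how PABP1 bound these mRNAs could move the median difference of −1.07 in the same way, so these sources cannot be told apart there. Binding by Msi1 that was alike in both experiments cancels in that difference.

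Ribosomal protein and oxidative phosphorylation lists were called lower with Msi1 than with both controls by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.161 to 0.345), and 19 of 80 oxidative phosphorylation genes were higher than with GFP against 52 lower. The loess curve as the whole cause is argued against for ribosomal proteins, whose medians stayed at −1.08 or lower with median centring. For oxidative phosphorylation against GFP the call may depend on the curve, since median centring left −0.10 and ended it, while the other scalings left −0.58 to −0.38. Bright probes in general are argued against, as 0 percent of 10000 random lists matched on signal had a median as low as the ribosomal proteins in either comparison. A property of Msi1-bound RNA and a single Msi1 RNA preparation used in both experiments both predict ratios that go together, as they did (r = 0.788 across the ribosomal protein genes), and cannot be told apart.

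The EVX1 probe was at least 52-fold lower with Msi1 than with GFP. A change of all EVX1 transcripts alike is argued against, since the gene's other probe gave −0.73. Sequence of the GFP construct on this probe is a candidate source, but the Msi1 channel, which held no such construct, also lay 2.90 higher on the log2 scale in the GFP experiment than in the PABP1 experiment. Leakage from the saturated GFP channel or a shared source could give that, and without the probe's sequence the source stays open. No biological explanation was tested for it.

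More genes changed side between the controls, by the limma test of the difference. JUN differed by −2.66, IRF7 by −1.66, IGSF8 by −3.60, CRTC1 by −3.53, BBC3 by −3.15 (its dimmer probe gave ratios of −0.64 and 1.05) and NOTCH2 by −1.85, all lower than GFP and higher than PABP1. The kinase gene CSNK1E, whose probe was saturated on up to 2 arrays of an arm, differed by about −2.04, the replication gene MCM7 by −1.59, and the translation genes EIF4G1 and EEF2 by −1.99 and −1.88, in the same direction. EEF2 had fewer than 4 usable arrays over GFP. A dimmer EIF4G1 probe gave −1.77 over GFP and 0.10 over PABP1, the latter not called (adjusted p = 0.561 with limma). In the other direction MED13L, with fewer than 4 usable arrays over GFP, differed by 3.09 and COXFA4, a complex IV subunit, by 2.14. Over all genes, 590 were higher than GFP and lower than PABP1, and 551 the reverse. List medians of the difference were 0.85 for oxidative phosphorylation (0.64 to 1.51 across scalings), 0.56 for histones (0.47 to 0.87), 0.23 for proteasome subunits (0.14 to 0.81) and 0.17 for ubiquitin-conjugating enzymes (0.17 to 0.48). They were −0.23 for Wnt pathway genes (−0.37 to −0.14), −0.52 for immediate early genes (−0.98 to −0.48) and −1.07 for heat shock genes (−1.14 to −0.38). Camera called each at the preset correlation and none with an estimated correlation (adjusted p = 0.0737 to 0.42).

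Of 187 groups of 4 values looked at, 11 held a value far from the others, where chance gives about 1 in 20. Against GFP, replicate 2 with Msi1 in Cy3 stood apart for DEPDC1 (1.31), JAG2 (−1.01) and PSMC3 (−1.20), replicate 2 with Msi1 in Cy5 for IER5 (−0.18), and replicate 1 with Msi1 in Cy5 for CACNG6 (−2.80). Against PABP1, replicate 1 with Msi1 in Cy3 stood apart for MSI1 (−1.17, the others −0.51 to −0.40), and replicate 1 with Msi1 in Cy5 for DHRS2 (2.38) and CRTC1 (1.74). Replicate 2 stood apart for FZD5 (1.24) and E2F3 (1.95) with Msi1 in Cy3 and for RNF149 (2.02) with Msi1 in Cy5.

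Turning the signs of arrays gave other groupings. The real grouping called 9638 genes against GFP, the highest other 139, and 1 of 8 groupings called as many. Against PABP1 the values were 10715 and 85, again 1 of 8, and 8 groupings are too few for a share under 0.05. For the difference, 1 of 35 splits of the 8 arrays called as many as the real 7833, the highest other calling 0. All other splits mix the experiments and so move their difference into the spread. The 0 thus shows that arrays of an experiment resembled each other more than those of the other experiment, and is no measure of chance. The same way against both controls were 7006 genes, reached by 1 of 100 sign patterns. Turning some arrays of an experiment likewise moves the ratios they share into the spread, so chance is not measured here either. The highest other, 923, had a whole experiment turned, which counts genes called in opposite directions against the controls. Chance between cultures or RNA preparations, or a single Msi1 RNA used throughout, was not tested by these groupings.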

How the results depend on the processing

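The alternatives here were planned. All 6 counts of genes stayed within 1.5 times under every alternative except the 2-fold threshold, which left 779 higher and 1491 lower against GFP, 1066 higher and 1838 lower against PABP1, 365 higher against both and 1466 that differed, since it removes small ratios. Leaving out single arrays gave 4082 to 4763 higher and 4543 to 5382 lower against GFP, 4764 to 5079 and 5365 to 5628 against PABP1, 3012 to 3324 higher against both and 6964 to 7871 that differed. An orientation left with 1 array was assumed to vary like the others. The share of calls that were higher lay between 46.2% and 52.6% across alternatives other than the 2-fold threshold (34.3% and 36.7%), and was 47.0% and 47.2% as reported.

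Camera's 18 list calls became 11 with median centring and 0 with an estimated correlation, and 16 to 18 without single arrays. The cause of these falls was not tested. A higher estimated correlation cannot be the reason in every list. That of the ubiquitin-conjugating enzymes was −0.022, below the preset 0.01, yet camera's unadjusted p against GFP rose from 0.00229 to 0.0177. Proteasome subunits and translation factors against GFP moved to medians of 0.01 and 0.03 with median centring. Across scalings, medians of other called lists against GFP ranged from −0.90 to −0.34 (heat shock), −0.58 to −0.10 (oxidative phosphorylation), 0.31 to 0.55 (ubiquitin-conjugating enzymes), 0.18 to 0.50 (histones), 0.13 to 0.47 (ZNF genes) and 0.50 to 0.79 (splicing proteins). Against PABP1 they ranged from 0.17 to 0.53 (Wnt pathway), −0.31 to −0.12 (histones), 0.14 to 0.41 (ZNF genes), −0.56 to −0.25 (proteasome) and 0.33 to 0.74 (immediate early genes). Lists not called moved too, among them against GFP the cell cycle (0.08 to 0.29), apoptosis (0.12 to 0.35), Notch pathway (−0.22 to −0.03), interferon response (0.04 to 0.49) and markers of other tissues (−0.50 to −0.13), the last reaching −0.64 against PABP1. DCX against GFP, never called, changed sign without background correction (0.005) and with Agilent's processed signals (0.12), and ranged from −0.032 (without replicate 1 with Msi1 in Cy3) to 0.014 (without replicate 2 with Msi1 in Cy5, adjusted p = 0.89 from limma) without single GFP arrays. The cause of this was not tested either. MSI2 against GFP gained the call under 4 alternatives, and MALAT1 against GFP lost it at the 0.01 threshold and without 3 of the GFP arrays in turn. Over the named genes, 3711 combinations of gene, comparison and alternative kept direction and call, 18 lost the call, 4 gained it and 3 changed sign, and for called lists 372 kept it and 53 lost it.

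The labels do not say that replicate numbers pair arrays. Deviations of same-numbered arrays of an experiment correlated at 0.012 and −0.143 across genes. The fit with the replicate block, which is also the scan day, estimated a correlation of −0.152 within blocks. It gave 4693 higher and 5266 lower against GFP, 5204 and 5840 against PABP1, 3420 higher against both and 8291 that differed, and moved no call of a named gene. A negative correlation within blocks lowers the SE of a ratio, so these larger counts add no evidence for the calls. Averaging the block lost the call of MALAT1 against GFP (adjusted p = 0.052 from limma).

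The motif search in 3' untranslated regions and its alternatives were not run, since no transcript sequences were used here. Fitting each experiment alone gave no test of the difference. A separate slide block was not possible, as each array had its own slide. Signal over background limits the dimmest genes, and DCX, for example, was well above background on 2 of 4 arrays of the Msi1 channel in the PABP1 experiment.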

Other observations

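The gene groups and tests in this part were chosen after the results were seen. Mitochondrial ribosomal protein genes are encoded in the nucleus. Against PABP1, 54 of 76 were lower and 10 higher, also adjusted over the list alone, with a median of −0.61 that stayed between −0.63 and −0.47 across scalings (camera adjusted p = 3.78e-07, and adjusted p = 0.283 with an estimated correlation). Against GFP, 36 were lower and 30 higher, or 36 and 31 adjusted over the list alone, and the median of −0.04 reached 0.24 with median centring (adjusted p = 0.6, and adjusted p = 0.798 with an estimated correlation). MRPL41 was at −2.17 ± 0.080 and −2.71 ± 0.080 over GFP and PABP1, MRPL28 at −2.08 ± 0.063 and −2.71 ± 0.063, and MRPL13 at 1.60 ± 0.051 and 0.68 ± 0.051 (limma, 4 arrays each).

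Sm proteins and some LSM proteins form the cores of small nuclear ribonucleoproteins. Their list also took in proteins outside these cores, among them SNRPA, SNRPA1, SNRPB2, SNRPC, LSM1 and LSM12. Its members were lower than with PABP1 in 15 of 22 and higher in 4, also adjusted over the list alone, with a median of −0.62 (camera adjusted p = 0.00936, and adjusted p = 0.283 with an estimated correlation). Against GFP, 10 were higher and 11 lower, or 11 and 11 adjusted over the list alone, and the median of −0.16 changed sign across scalings (adjusted p = 0.741, and adjusted p = 0.798 with an estimated correlation). Over PABP1, SNRPD2 was at −2.77 ± 0.081 and SNRPG at 1.36 ± 0.070. RAB GTPases, which steer vesicle traffic, were higher than with GFP in 25 of 52 and lower in 8, also adjusted over the list alone. Their median of 0.14, which ranged from 0.13 to 0.33 across scalings, lay above 99.9% of signal-matched random lists (camera adjusted p = 0.0709, and adjusted p = 0.385 with an estimated correlation). Against PABP1, 21 were higher and 17 lower, also adjusted over the list alone, with a median of 0.01 that lay above 84.2% of matched lists (adjusted p = 0.413, and adjusted p = 0.57 with an estimated correlation). RAB10 was at 1.58 ± 0.059 over GFP and 0.99 ± 0.059 over PABP1.

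The other lists of this kind were not called by camera against either control, where the lowest adjusted p was 0.142 (adjusted p = 0.561 with an estimated correlation). DEAD and DEAH box helicases were higher in 12 and lower in 24 of 49 against GFP and in 19 and 20 against PABP1, also adjusted over the list alone. Aminoacyl-tRNA synthetases were higher in 9 and lower in 18 of 31 against GFP, or 9 and 19 adjusted over the list alone, and in 11 and 15 against PABP1, or 12 and 15. RNA polymerase II subunits were higher in 4 and lower in 7 of 11 against GFP and in 3 and 6 against PABP1, chaperonin subunits in 2 and 4 of 7 and in 4 and 2, and cullins and F-box proteins in 22 and 19 of 56 and in 26 and 20, all also adjusted over the list alone.

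Several of the highest genes against both controls, among them TMCO1, SPCS2 and ARL6IP1, encode membrane proteins of the endoplasmic reticulum, and a hypothesis was that mRNAs of membrane proteins may be enriched with Msi1 in general. Solute carriers had medians above 42.6% of signal-matched random lists against GFP and 69.2% against PABP1, which argues against it. TMEM genes lay above 98.8% against GFP, which goes with it, but above 59.5% against PABP1, and camera called them against neither (adjusted p = 0.142 and 0.943, and adjusted p = 0.561 and 0.954 with an estimated correlation). Of 149 TMEM genes, 64 were higher and 49 lower than with GFP, also adjusted over the list alone, and 54 and 58 against PABP1, or 54 and 59 adjusted over the list alone. The TMED cargo receptors, signal peptidase and translocon genes as a group also failed, above 48.8% of matched lists in the weaker comparison. Of their 23 members, 11 were higher and 7 lower against GFP and 8 and 11 against PABP1, also adjusted over the list alone (camera adjusted p = 0.193 and 0.831, and adjusted p = 0.561 and 0.954 with an estimated correlation). TMED10 was at 2.00 ± 0.070 and 1.11 ± 0.070, while SSR4 was among the lowest genes.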
